A study of Mus musculus with 9 samples.

How the data were processed

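The 9 samples are total RNA from E12.5 retinas of CD-1 mice. Per the labels' protocols, pairs of GFP-positive optic cups were dissected and dissociated with TrypLE Select, RNA was extracted with an RNeasy Micro kit, and libraries were made with the TruSeq RNA kit. No cell sort is named. Groups were taken from the labelled genotypes, with 3 heterozygote, 3 mutant and 3 knock-in samples.

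Per the submitters' processing notes, reads were processed with Bowtie2, Cufflinks and Cuffdiff on mm10; versions are not given in the sources used here. The authors deposited one table per comparison, mutant against heterozygote and knock-in against mutant, with one row per assembled transcript. Per the file headers each table holds an RPKM value for each of its 2 groups, that is read density scaled to transcript length and to mapped reads. It also holds the authors' log2 fold change, their test statistic (a score without fixed range, per the file headers), and the deposited p-value and q-value. Replicates were pooled into these values by the authors, so nothing here was computed per sample. The depth per sample is unknown, since RPKM values assigned to overlapping transcripts do not return read numbers. The tables hold 27311 and 26586 transcripts, of 12247 and 11989 gene symbols, and the lower limit on expression that they show was 0.906 and 1.04 RPKM in the higher group of a row.

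The deposited q-values equalled the Benjamini-Hochberg adjustment of the p-values over all rows of the same table to within 5.26e-07. The smallest p is 5e-05, held by 125 and 128 transcripts, so no q is below 0.0109 and 0.0104. Log2 ratios were recomputed from the RPKM values without a pseudocount and equalled the deposited ones to within 0.0041. Where a group was at 0 no ratio is given. The tables had passed through a spreadsheet: 57 and 55 transcripts carry a date in place of a symbol, and 116 and 117 carry no symbol. These stayed in the transcript counts and out of everything done by gene. Transcript numbers differ between the tables, so genes were joined by symbol. Coordinates are those of the authors' loci on mm10, given from base 1; a locus can hold several transcripts or overlapping genes. Exons and untranslated sequence of Neurog2 came from the GENCODE annotation of the same assembly.

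The test of single transcripts is the authors' own, with calls at q of 0.05 or less. A gene counts as called if any of its transcripts is, and its summed RPKM is the sum over its listed transcripts. In all, 20 gene lists were fixed before the data were examined: ganglion cell transcription factors, neuronal and axonal differentiation, bHLH factors, Notch pathway, retinal progenitors, cell cycle progression, cell cycle exit, precursors of photoreceptor, horizontal and amacrine cells, the GABAergic programme, p53 and apoptosis, stress and immediate early genes, pigment epithelium, lens, periocular mesenchyme, endothelium, blood, macrophages, surface ectoderm, optic stalk and ciliary margin, and sex-linked genes. Only 3 genes are in more than one list, none of them in the pigment epithelium, lens, blood or stress lists. For each list, direction and comparison a two-sided Fisher's exact test set calls inside the list against calls among all other measured genes, with Benjamini-Hochberg adjustment over all 80 tests; genes are not independent replicates. A list's median log2 ratio was placed among 10000 random lists matched in 20 bins of mean expression, as a description. The count adjusted over the list alone adjusts the authors' p-values over the transcripts of one list.

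The genes named were chosen by a rule fixed before the data were examined. It takes Neurog2; the 8 largest rises and 8 largest falls among called genes with at least 1 RPKM in either group and a finite ratio, leaving out predicted and small RNA genes; up to 4 called members of each list with the smallest p, or the 2 most abundant where none was called; and, of genes called in both comparisons, the 8 strongest with opposite directions and up to 4 with the same direction. The rule took 66 genes in the first comparison and 54 in the second; the text gives those that carry the description, and some of the items are not reported here. Names outside the rule are said to be so.

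Overlap of the comparisons was set against simulations in which 3 unchanged groups of normal values share the middle group, with the observed numbers of calls, over 1000 rounds. For the covariance the simulated errors came from the authors' test, either as the ratio divided by the test statistic or as the ratio divided by the normal quantile of the p-value. The list test was tested on simulated data at the real gene numbers and at each comparison's share of genes called lower. The adjustment was tested at the real transcript numbers. With 40% of a 20-gene list called, the list test passed in 99% of 200 rounds for each comparison at 0.05 divided by the number of tests. With 20% called it passed in 52.5% of rounds for mutant against heterozygote and 78% for knock-in against mutant, and with calls at random in 0%. In knock-in against mutant 124 genes were called higher and 76 lower, so its rates do not cover the tests of higher calls. The adjustment recovered 99.3% and 99.4% of 200 planted transcripts with 5.22% and 5.29% false calls. Most planted p-values were set below 5e-05, the smallest deposited p, so this recovery is not the sensitivity for real changes. Alternatives were another q threshold, a minimum fold, minimum RPKM values with p adjusted again, rows without a finite ratio left out, centred ratios, pseudocounts of 0.1 and 1 RPKM, other list backgrounds and other distances from Neurog2. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Tests that need values per sample were not used, and the designs written for such values were set aside.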

Results

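RNA was sequenced from the retinas of CD-1 mouse embryos at E12.5, a day of gestation when the retina is mostly dividing progenitors and the first retinal ganglion cells are forming. The 9 samples fall into 3 groups of 3, set by the alleles at Neurog2, which encodes a proneural transcription factor of the basic helix-loop-helix (bHLH) family. Heterozygotes carried GFP at one Neurog2 allele, mutants carried GFP at both, and the knock-in group carried GFP at one allele and an inserted coding sequence at the other. The files give one RPKM value per transcript and group, with no values per sample, so no spread between replicates can be printed beside a value, and the depth per sample is unknown. The error enters through the test in the authors' deposited tables, made by Cuffdiff. Each named transcript called changed without a printed q had the lowest q of its table, 0.0109 for mutant against heterozygote and 0.0104 for knock-in against mutant. The labels do not say whether the 3 samples of a group came from separate litters, so these tests measure only the spread between the samples.

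The targeted gene was examined first. Neurog2 (mm10 chromosome 3, 127633135 to 127635631, 2 exons) was at 30.2 RPKM in the heterozygote and 36.2 RPKM in the mutant, and this difference did not pass the test (p = 0.081, q = 0.993 in the authors' deposited table). Its untranslated sequence makes up 64.6% of the annotated transcript, and the tables do not separate coding from untranslated signal, so the Neurog2 value does not check whether the coding part was lost. In the knock-in group Neurog2 was at 112 RPKM against 35.5 RPKM in the mutant, a rise of 1.66 on the log2 scale. Because Neurog2 was not lower in the mutant group and was higher in the knock-in group, which has no intact Neurog2 allele by its label, the groups are written below as mutant-labelled and knock-in-labelled.

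**Figure D1:**
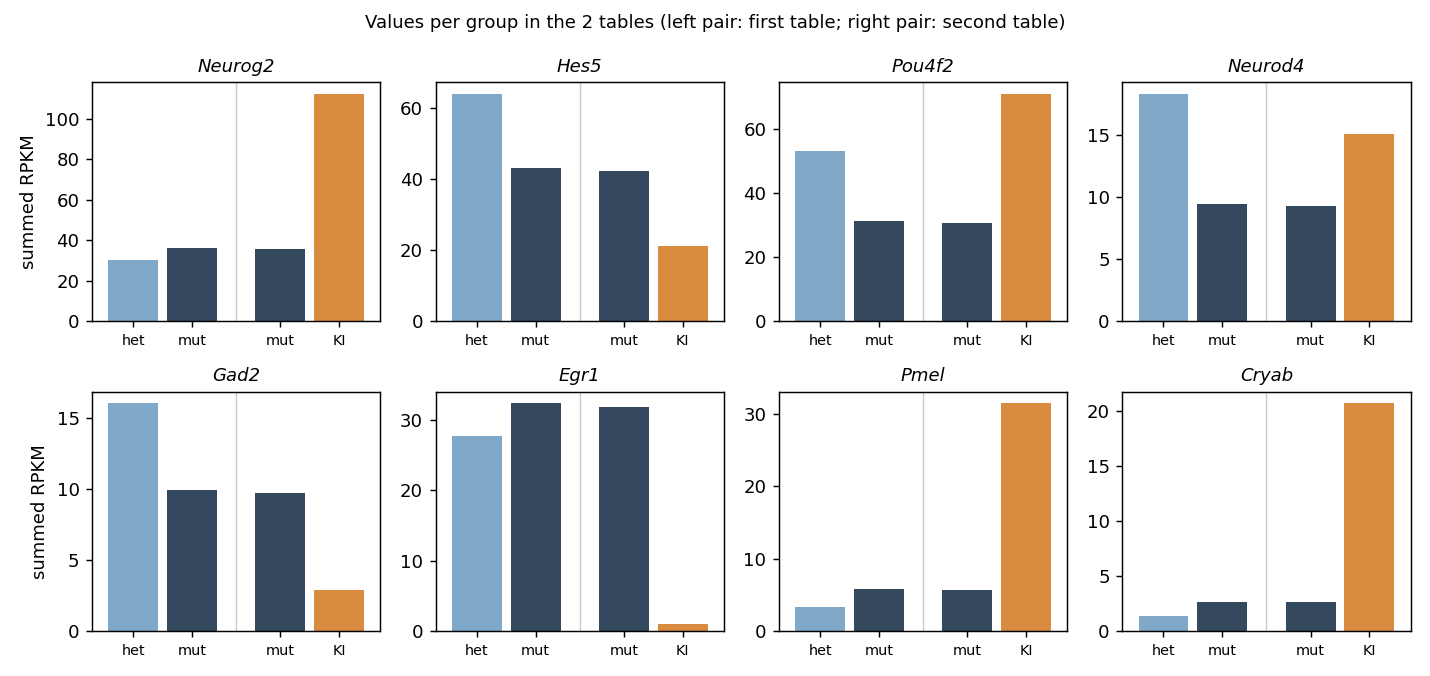
RPKM per group, summed over the listed transcripts of a gene, for 8 genes in the 2 tables (het, heterozygote; mut, mutant-labelled; KI, knock-in-labelled). Each bar is the authors' single value for a group, so there are no error bars. Neurog2 stood at 112 RPKM in the knock-in-labelled group, and Egr1 at 1.03 RPKM there against 31.8 RPKM in the mutant-labelled group.

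The comparison of mutant-labelled with heterozygote retinas asks what the second GFP allele at Neurog2 changes. Genes of neurons fell. Of 29 measured genes of neuronal and axonal differentiation, 18 were called lower and none higher, and the list's median log2 ratio was -0.995. Of 16 measured transcription factors of retinal ganglion cells, 6 were called lower and none higher, with a median of -0.82. The lists of retinal progenitor genes and of cell cycle progression had no calls. In all, 166 of 27311 transcripts were called, 136 of them lower and 30 higher, which are 134 and 30 genes. At an unadjusted p under 0.05 the authors' deposited table holds 1415 transcripts, where 1366 would be expected by chance.

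Among the ganglion cell factors, Pou4f1 fell from 7.54 to 2.66 RPKM and Irx2 from 30.9 to 11.5 RPKM. Barhl2 fell from 10.6 to 5.07 RPKM. Pou4f2 (chromosome 8, 78433010 to 78436645), which drives ganglion cell differentiation, fell from 53.1 to 31.1 RPKM, a log2 ratio of -0.77. Calls in the lower direction were more frequent in this list than outside it (two-sided Fisher's exact test, p = 2.24e-07 adjusted over the 80 list tests). Adjusted over the list alone, 11 members were lower and 1 higher. Among the neuronal genes, the neurofilament genes Nefl and Nefm fell from 42.8 to 14.7 RPKM and from 69.0 to 26.3 RPKM. Syt4, a synaptotagmin, fell from 2.98 to 0.942 RPKM, and Slc17a6, a vesicular glutamate transporter, from 1.98 to 0.713 RPKM. Lower calls were again in excess in this list (adjusted exact p = 3.88e-27), and 28 of its 29 members had lower summed RPKM. Adjusted over the list alone, 23 of its genes were lower.

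Of 14 proneural and neuronal bHLH factors and partners, 5 were called lower (adjusted exact p = 4.31e-06). Nhlh1 fell from 14.5 to 5.26 RPKM, Nhlh2 from 15.2 to 6.32 RPKM and Neurod4 from 18.3 to 9.43 RPKM. The other two, named after their values were seen, were Olig2 and Insm2, with q = 0.0424 and q = 0.0286 in the authors' deposited table. Factors of other early retinal neurons fell as well. Prdm13 (amacrine cells) fell from 2.33 to 0.712 RPKM and Onecut3 from 3.81 to 1.24 RPKM. Onecut2, a factor of horizontal cells, fell from 16.6 to 7.74 RPKM (q = 0.0367 in the authors' deposited table), and Prdm1 (photoreceptor precursors) from 17.8 to 10.8 RPKM. These 4 are of 12 measured members (adjusted exact p = 8.45e-05). In the GABAergic list, 2 of 5 measured genes fell (adjusted exact p = 0.0103). Gad2, which makes GABA, fell from 16.0 to 9.91 RPKM and Sp8 from 4.84 to 2.99 RPKM (q = 0.0424 in the authors' deposited table).

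None of 23 measured retinal progenitor genes was called. Their median log2 ratio was 0.22, at percentile 99.5 of 10000 random lists of like expression. The most abundant, Sfrp2 and Fgf15, were at 1027 and 336 RPKM in the heterozygote and 1304 and 402 RPKM in the mutant-labelled group. None of 33 genes of cell cycle progression was called (median 0.10, percentile 67.4), nor was any of 23 Notch pathway genes (median -0.13, percentile 0.61). Adjusted over the list alone, 3 Notch pathway genes were lower. One of 15 genes of cell cycle exit fell, Btg2, from 63.4 to 40.9 RPKM. One of 15 stress and immediate early genes fell, Hspa1a, from 7.14 to 3.81 RPKM; its reads cannot be told apart with certainty from those of its near-identical neighbour. The 12 measured genes of the p53 pathway and apoptosis and the 14 of optic stalk and ciliary margin had no calls. Nor did the lists of other tissues, with 6 genes of pigment epithelium, 12 of lens, 5 of periocular mesenchyme, 2 of endothelium, 5 of blood, 1 of macrophages and 2 of surface ectoderm. The pigment epithelium median was 0.51 (percentile 99.8), the lens median -0.41 (percentile 0.13) and the blood median -0.51 (percentile 6.43). Adjusted over the list alone, 3 pigment epithelium genes were higher and 1 lower, and 1 lens gene was higher and 1 lower. Of the sex-linked genes, the most abundant transcript of Eif2s3y was at 12.52 RPKM in the heterozygote and listed at 0 in the mutant-labelled group, and that of Xist was at 112 and 337 RPKM. Summed over transcripts, the other 3 measured Y-linked genes, named after their values were seen, were at 12.8 (Kdm5d), 4.56 (Ddx3y) and 3.48 RPKM (Uty) in the heterozygote and at 0, 0.0104 and 0.0168 RPKM in the mutant-labelled group. None of these differences passed the test, but the mutant-labelled values show next to no male tissue, so the groups differ in sex as well as in genotype. Calls on X and Y were 4 of 452 tested genes, against 160 of 11795 on other chromosomes (two-sided Fisher's exact test, p = 0.531). Because Xist and the Y-linked genes were themselves not called, this count cannot measure or exclude an effect of sex.

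Outside the lists, the largest falls were those of Xkr7 (1.36 to 0.290 RPKM), Pappa2 (2.05 to 0.582 RPKM) and Akap6 (3.90 to 1.18 RPKM). Leaving out predicted genes and a pseudogene, the largest rises of genes whose summed value followed the transcript were those of Smoc1 (6.73 to 17.7 RPKM), Gje1 (20.7 to 52.4 RPKM), Kcnk1 (8.12 to 18.7 RPKM), F5 (1.98 to 4.49 RPKM) and Col9a1 (17.5 to 37.9 RPKM). Rps19-ps3, the pseudogene, which shares sequence with its parent, went from 6.02 to 19.2 RPKM. For Tbl2 and Twf1 a single transcript was called up, by 4.53 and 2.21 on the log2 scale, while the summed RPKM of the gene differed by 0.11 and 0.03. The Twf1 transcript had q = 0.0367 in the authors' deposited table.

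**Figure D2:**
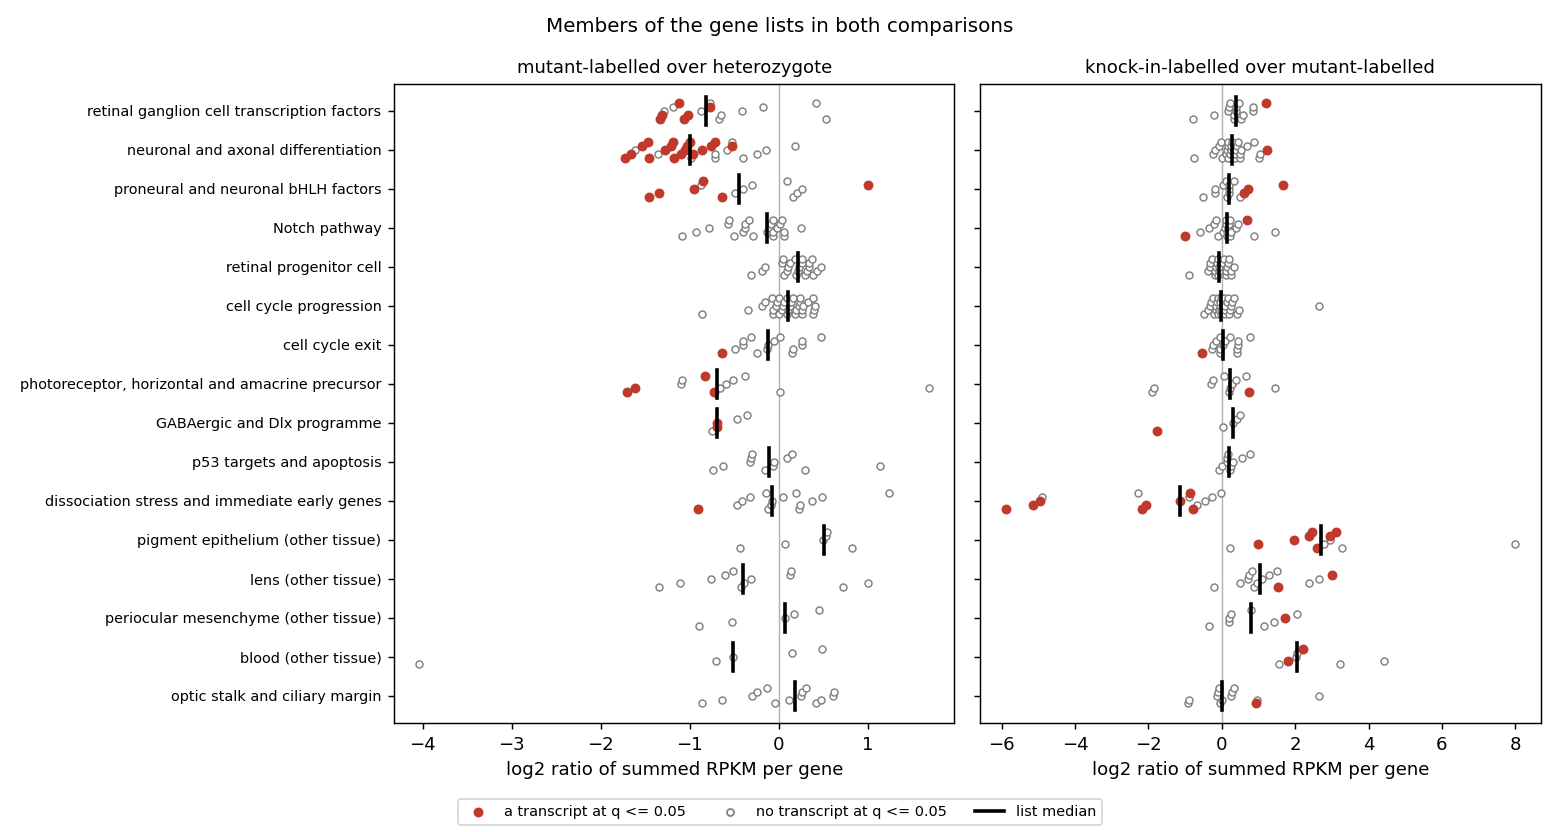
Log2 ratio of summed RPKM for the measured members of the gene lists with at least 3 of them, without sex-linked genes and genes with no finite ratio, mutant-labelled over heterozygote (left) and knock-in-labelled over mutant-labelled (right). Each point is a gene, filled where a transcript passed q of 0.05, and bars mark list medians. Neuronal lists lie left of 0 on the left panel (medians -0.995 and -0.82), and on the right panel the stress list lies left of 0 (median -1.13) and the pigment epithelium list right of it (median 2.69).

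The comparison of knock-in-labelled with mutant-labelled retinas asks what the knock-in at a Neurog2 allele changes where no intact Neurog2 allele remains. Pou4f2 rose 2.32-fold, from 30.5 to 70.9 RPKM. The median of the neuronal genes was higher, but few single ones passed the test. Immediate early genes fell, Fos from 24.0 to 0.536 RPKM and Egr1 from 31.8 to 1.03 RPKM. Genes of pigment epithelium, lens and blood rose, Pmel from 5.72 to 31.5 RPKM, Cryab from 2.58 to 20.7 RPKM and Hbb-y from 27.1 to 94.7 RPKM. In all, 201 of 26586 transcripts were called, 125 higher and 76 lower, which are 124 and 76 genes, and 1862 transcripts had an unadjusted p under 0.05 in the authors' deposited table, where 1329 would be expected by chance. The sample titles carry one number for the heterozygote and mutant samples and another for the knock-in samples. If it marks a litter or batch, it cannot be separated from the knock-in label.

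The neuronal lists held few calls. Pou4f2 was the one call among 15 ganglion cell factors, whose median log2 ratio was 0.38 (percentile 99.98). Rbpms, an RNA-binding protein of ganglion cells, was the one call among 28 genes of neuronal and axonal differentiation, from 5.40 to 13.9 RPKM; their median was 0.27 (percentile 100). Adjusted over the list alone, 2 and 6 genes of these lists were higher and 1 and 1 lower. Higher calls were 1 of 15 genes against 123 of 11974 others, and 1 of 28 against 123 of 11961. With 1 call each, neither list passed (adjusted exact p = 0.580 and 0.879), which does not exclude an excess. Of 14 bHLH factors and partners 3 rose (adjusted exact p = 0.00413), Neurog2 itself, Neurod4 from 9.26 to 15.1 RPKM and Insm2 from 10.6 to 16.0 RPKM (q = 0.0363 in the authors' deposited table). Without Neurog2, an alternative chosen after the data were seen, this list no longer passed (adjusted exact p = 0.0615).

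In the Notch pathway, with 22 measured genes, the Notch target Hes5 fell from 42.3 to 21.3 RPKM and the receptor gene Notch3 rose from 4.96 to 7.93 RPKM. A transcript of Onecut2 rose from 15.5 to 25.4 RPKM and was the one call among 12 precursor genes. By its mutant value it was another transcript than the one that fell to 7.74 RPKM in the first comparison. Gad2 fell further, from 9.72 to 2.86 RPKM, the one call among 5 genes of the GABAergic list. Tob1 fell from 26.5 to 18.3 RPKM (q = 0.0463 in the authors' deposited table), the one call among 15 genes of cell cycle exit. None of 23 progenitor genes (median -0.07), 33 genes of cell cycle progression (median -0.01) or 10 p53 and apoptosis genes (median 0.20) was called. Members of the cell cycle progression list ranged from -0.49 to 2.64. The highest was Ccnd2, named after its value was seen, with summed RPKM of 11.7 and 73.1. None of these lists passed Fisher's exact test in this comparison.

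All 15 measured stress and immediate early genes had lower summed RPKM in the knock-in-labelled group, and 8 were called (median -1.13; adjusted exact p = 4.44e-13). Fosb fell from 14.8 to 0.421 RPKM and Hspa1a from 3.74 to 0.835 RPKM. Cyr61, an immediate early gene outside the list, fell from 16.8 to 1.79 RPKM. All 12 measured pigment epithelium genes were higher and 7 were called (median 2.69; adjusted exact p = 2.16e-10). Dct, Tyrp1, Gpnmb and Slc45a2 rose from 2.40 to 20.9, from 0.841 to 5.09, from 1.22 to 6.88 and from 0.165 to 1.28 RPKM, the last with q = 0.0363 in the authors' deposited table. Of 15 lens genes 14 were higher and 3 were called (median 1.03; adjusted exact p = 0.00449). Cryaa rose from 13.2 to 38.1 RPKM, and Foxe3 was listed at 0 in the mutant-labelled group and at 1.05 RPKM in the other. All 7 measured blood genes were higher and 2 were called (median 2.04; adjusted exact p = 0.0172), Hbb-y and Hba-x, the latter from 5.11 to 20.8 RPKM (q = 0.0413 in the authors' deposited table). These globin genes have close paralogs. A gene is listed only where one group reaches about 1 RPKM, so a high knock-in value can bring it into the table; among members listed in the other table as well, 6 of 6 pigment epithelium, 11 of 12 lens and 5 of 5 blood genes were higher. Of 9 periocular mesenchyme genes 8 were higher (median 0.80, percentile 99.96), and 5 were higher when adjusted over the list alone, but Lum was the one call (1.22 to 4.06 RPKM; adjusted exact p = 0.486). Of the mesenchyme genes listed in the other table as well, 4 of 5 were higher. Single calls in other lists were Krt18 among 2 surface ectoderm genes (2.28 to 8.06 RPKM) and Gja1 among 13 optic stalk and ciliary margin genes (7.78 to 14.9 RPKM). The 2 endothelial genes and the 1 macrophage gene measured had no calls and lower summed values (log2 ratios of -0.32 for Kdr, -0.24 for Egfl7 and -0.39 for Cd68). The most abundant Eif2s3y transcript was listed at 0 in the mutant-labelled group and at 17.3 RPKM in the knock-in-labelled group, and that of Xist was at 331 and 101 RPKM. Kdm5d, Uty and Ddx3y, again named after their values were seen, were at 19.3, 9.44 and 8.81 RPKM in the knock-in-labelled group, summed over transcripts, and at 0, 0.0165 and 0.0102 RPKM in the mutant-labelled group. No sex-linked gene was called, but sex differs between these groups as well. Calls on X and Y were 6 of 440 tested genes, against 194 of 11549 elsewhere (same exact test, p = 0.848). For the same reason this count cannot measure or exclude an effect of sex.

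Pianp had the largest rise with a finite ratio among the named genes that were called, from 0.456 to 5.74 RPKM, and Dennd1c went from 0.513 to 3.30 RPKM. Of 63 called transcripts in genes with several listed transcripts, 16 had a summed gene value that moved less than 1.2-fold or the other way. Upf2, Acox3 and Ddx17 are among them, with log2 ratios of -4.25, -4.08 and -2.26 for the transcript and of -0.06, -0.10 and -0.23 for the summed gene. The Acox3 transcript had q = 0.0363 in the authors' deposited table. The summed change of Pofut1, whose called transcript rose by 3.27, was 0.31. In the other comparison 3 of 41 such transcripts behaved this way.

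The mutant-labelled samples are in both tables, so the tables can be set side by side to ask whether genes that changed with the second GFP allele moved back in the knock-in-labelled group. The tables were normalized separately; over 4894 genes with a single transcript in both, 99.04% of the ratios of the 2 mutant values lay within 0.05 of their median of 0.03 on the log2 scale. Of 11848 genes in both tables, 20 were called in opposite directions, 17 of them lower and then higher. This counts genes, and the called transcript can differ. The called transcripts had mutant values of 7.74 and 15.5 RPKM for Onecut2, and of 24.5 and 28.2 RPKM for Flrt2. For these genes different transcripts were thus called, although the summed values also moved both ways. Pou4f2 went from 53.1 RPKM in the heterozygote to 31.1 and then to 70.9 RPKM, and Neurod4 from 18.3 to 9.43 and then to 15.1 RPKM. Serpini1, Myo16, Camk2n1, Rab3c and a transcript of Acsl6 likewise fell, and then rose by 0.73 to 1.45 on the log2 scale; in the authors' deposited table the rise of Rab3c had q = 0.0254 and the fall of the Acsl6 transcript q = 0.0204. The 3 genes called higher and then lower were Gje1, Flrt2 and Tmem60, the last from 42.5 to 73.7 and then from 72.3 to 29.3 RPKM; the later falls of Gje1 and Flrt2 both had q = 0.0413 in the authors' deposited table. The genes called the same way in both were Gad2 and Hspa1a, lower in both, and Gm1821, a predicted gene, higher in both. One transcript without a symbol, at the 3' end of Dcc (chromosome 18, 71253632 to 71254432), an axon guidance receptor, fell from 123 to 47.4 RPKM and then rose from 51.6 to 156 RPKM.

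Sharing the mutant samples produces opposite calls without any effect, because a chance low value there lowers one ratio and raises the other. In simulations of unchanged groups that share those samples, with as many calls, 19.4 opposite calls arose on average (95% of rounds gave 12 to 27.0), against 20 observed. Independent lists of these sizes would share 1.39. Of the same-direction calls 3 were observed, 0 in the simulations and 1.08 for independent lists. Of 153 genes called in the first comparison and listed in both, 126 had summed values that moved the other way in the second, 82.4% (exact binomial interval 75.4% to 88.0%, which treats genes as independent). The simulations gave 94.1%. The median share of the log2 change that was undone was 0.33, and the median log2 ratio across the tables, knock-in-labelled over heterozygote, was -0.60 for the genes called lower. No simulated value is given for this share. Sharing the mutant samples would alone put it above 0, so it does not measure a return. Across 3039 single-transcript genes of at least 5 RPKM, which are not independent replicates, the covariance of the 2 log2 ratios was -0.058. It was -0.10 in simulations whose error came from the authors' p and -0.58 with the error from their test statistic. The observed opposite movement was thus no larger than in these simulations. Their covariance ranges were -0.14 to -0.072 and -0.90 to -0.31, so the observed covariance was weaker than both. Either simulated error may therefore be too large for these data. The simulations also treat every called gene as unchanged, so they cannot decide whether genes moved back. The Y-linked genes and Xist went one way and back as well, so a sex difference runs along with any return.

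**Figure D3:**
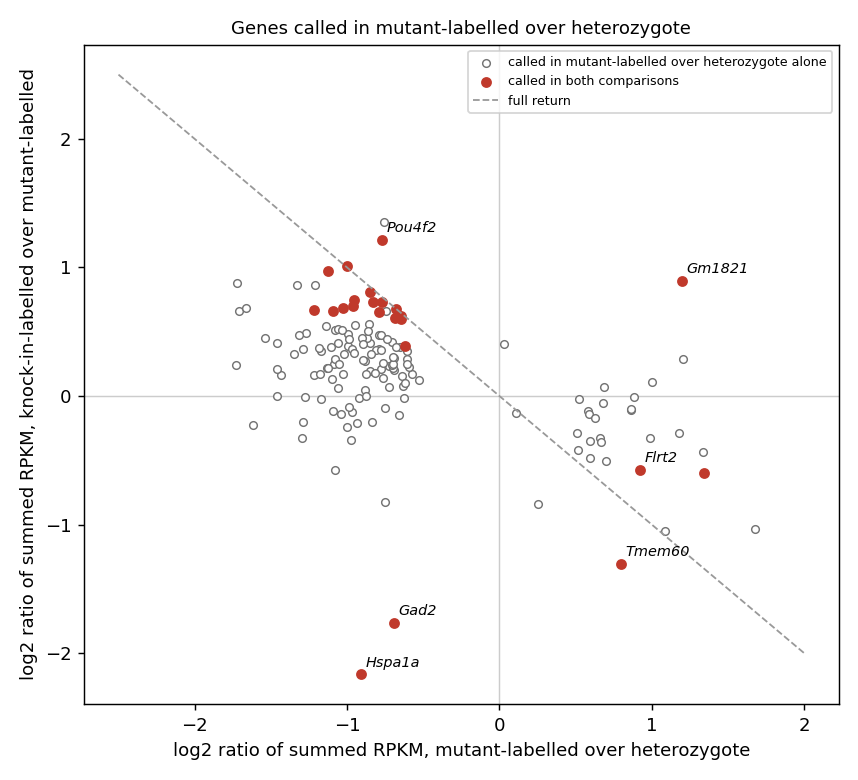
Log2 ratios of summed RPKM for the 153 genes called in mutant-labelled against heterozygote retinas and listed in both tables. The horizontal axis is mutant-labelled over heterozygote, the vertical axis knock-in-labelled over mutant-labelled, filled points were called in both, and the dashed line marks a full return. Of these genes 126 lie on opposite sides of 0 on the 2 axes, 82.4%. Simulated unchanged groups that share the mutant samples gave 94.1%.

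Both engineered alleles sit at Neurog2, so calls near it were counted to see whether flanking DNA stood out. Within 10 Mb, 1 of 67 other tested genes was called in mutant-labelled against heterozygote retinas, against 163 of 12179 elsewhere (two-sided Fisher's exact test, p = 0.596). In knock-in-labelled against mutant-labelled retinas it was 1 of 62 against 198 of 11926 (same exact test, p = 1). The genes, named after their values were seen, were Hadh, from 30.3 to 45.6 RPKM (q = 0.0424 in the authors' deposited table), and Dkk2, from 0.404 to 1.88 RPKM.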

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

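The restriction to calls whose summed gene value moved at least 1.2-fold the same way, and the one that left out sex chromosomes and the other-tissue, stress and sex-linked lists, were chosen after the data were seen. Because the smallest deposited p is 5e-05, a threshold of 0.01 leaves 0 calls in both comparisons in either direction, 0 lists, and 0 opposite or same-direction calls; no share of returning genes can then be given. At 0.10 the calls in knock-in-labelled against mutant-labelled retinas rose to 310, of which 196 were higher, the opposite calls to 35 and the same-direction calls to 5. Every other alternative run kept the counts within 1.5 times: 134 to 211 calls in the first comparison and 173 to 201 in the second. The first comparison stayed mostly lower under them, with 16.6% to 22.4% of its calls higher. With Neurog2 left out, chosen after the data were seen, 9 of the 10 lists passed, the bHLH factors of the knock-in comparison being lost at an adjusted exact p of 0.0615. Among genes listed in both tables, also chosen after the data were seen, all 10 passed. All 117 named values with a finite ratio kept direction and side of the threshold under pseudocounts, centring, a 1 RPKM minimum and a 0.10 threshold. The 92 at 5 RPKM or more did so under that minimum. Most of this was fixed in advance. Pseudocounts and centring leave the deposited q unchanged, and a pseudocount cannot reverse a ratio. A threshold of 0.10 cannot remove a call, and no listed row lies far below 1 RPKM in its higher group. None of 40 list medians changed sign with a pseudocount, which follows largely from the same limit. The share of genes that moved back was 82.4% under centring, and a pseudocount cannot change it. No paired analysis was possible because the tables hold no values per sample; leaving out replicates, other splits of the samples and count-based fits were not run for the same reason. Depth is unknown, so a gene that was not called may have been out of reach: the list test on simulated data at the size of the second comparison missed lists of which 20% were called in part of its rounds.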

Other observations

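Gene families outside the lists were examined after their members had been seen among the calls, as were all tests in this part. In mutant-labelled against heterozygote retinas the subunits of the nicotinic acetylcholine receptor were lower. Of 6 measured, 4 were called lower and all 6 had lower summed RPKM (two-sided Fisher's exact test, adjusted p = 4.04e-06 over 20 family tests). Chrna3 fell from 113 to 64.4 RPKM, Chrna4 from 67.5 to 41.4, Chrnb4 from 39.4 to 25.1 and Chrna5 from 3.10 to 1.34 RPKM. Chrna5, Chrna3 and Chrnb4 are neighbours on chromosome 9 (54980880 to 55048544). The test counts them as independent genes, and the family was picked for its calls, so its p is a description only. In the knock-in-labelled group all 5 measured were higher than in the mutant-labelled group, with none called. Of 79 cytosolic ribosomal protein genes, 78 were higher in the mutant-labelled group, with a median log2 ratio of 0.33, and 2 were called; the median was 0.31 after centring. They have many processed copies, so single values are uncertain.

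In knock-in-labelled against mutant-labelled retinas 5 of 41 measured replication-dependent histone genes were called lower (adjusted exact p = 5.62e-05), among them Hist1h4d, from 479 to 248 RPKM, and Hist1h2ak, from 81.2 to 38.3 RPKM. Copies of these genes share much of their sequence. The median of the family was -0.23, against 0.23 in the other comparison, where 1 was called higher. Of 15 genes of protein folding and entry in the endoplasmic reticulum 4 were called higher (adjusted exact p = 9.08e-05), Sec61b, Canx, Hspa5 and Pdia6, with log2 ratios of 0.98, 0.70, 0.58 and 0.51 and, for the last 2, q = 0.0320 and q = 0.0363 in the authors' deposited table; for Canx the summed gene value did not follow, with a log2 ratio of -0.01. Of 17 glycolysis genes Ldha and Pgam1 were called higher, which did not pass (adjusted exact p = 0.0636).

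Neurog2 signal was 3.16-fold the mutant-labelled level in the knock-in-labelled group. Heterozygote libraries under a wrong label would give a Neurog2 ratio near that of the heterozygote to the mutant-labelled group, 0.833, so the tables argue against that swap. RNA of the engineered allele may be counted under Neurog2 if it kept untranslated Neurog2 sequence, which is 64.6% of the annotated transcript. Without reads per exon this cannot be told apart from an effect of the genotype on the Neurog2 locus.

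Pigment epithelium, lens and blood genes were higher in the knock-in-labelled group. The lens and blood medians were lower in the mutant-labelled group than in the heterozygote (-0.41 and -0.51), with 8 of 12 lens and 3 of 5 blood genes lower. The others were higher in the mutant-labelled group, among them Cryab (1.31 to 2.63 RPKM) and Hbb-y (19.7 to 27.6 RPKM). Their later rise thus did not start from a low mutant value. The pigment epithelium median was higher in the mutant-labelled group (0.51). An even loss of retinal cells would raise every other tissue alike, but among genes listed in both tables the mean log2 ratio was 2.41 for 5 blood, 1.85 for 6 pigment epithelium, 1.203 for 12 lens, 0.98 for 2 surface ectoderm and 0.64 for 5 periocular mesenchyme genes, -0.28 for 2 endothelial genes and -0.39 for 1 macrophage gene. These 7 lists differed by more than shuffled gene labels give (permutation test over 33 genes, p = 0.0185). For the 4 lists with at least 5 genes the same permutation test gave p = 0.0335. Pigment epithelium against mesenchyme alone did not pass (exact permutation test, two-sided, p = 0.0736). The shuffle treats genes as independent, but genes of one tissue can move together in values pooled per group. These p-values are thus descriptions and cannot exclude an even loss as the whole cause. A candidate explanation is that more cells of tissues around the retina stayed with these cups. Of the 23 members of the 3 lists that the first table lists, 22 were higher, 95.7%. Abundant ones such as Pmel (31.5 RPKM), Cryaa (38.1 RPKM) and Hbb-y (94.7 RPKM) rose. These values restate the pattern, so they cannot favour this explanation over others. None of these members is in another list, no sort that would remove such cells is named, and a change of these tissues with the genotype or with sex, which differs between the groups too, stays open and was not tested.

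Immediate early and stress genes were lower in the knock-in-labelled group. If the mutant-labelled libraries alone had been raised, the 8 called members would be as much higher there than in the heterozygote; their median log2 ratio was -0.11 (range -0.91 to 1.24), against -2.11 for knock-in-labelled over mutant-labelled. Handling before lysis may have differed between the title numbers: the list median was -0.076 between the groups that share a number and -1.13 between those that do not. The number and the genotype go together in that comparison, so the explanations cannot be told apart.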
